A study of Bifidobacterium longum with 2 samples.

How the data were processed

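RNA was profiled in 2 cultures of *Bifidobacterium longum* strain BBMN68, an anaerobic Gram-positive gut bacterium. One culture received no bile (control) and the other received ox-bile, a preparation of cattle bile rich in detergent-like bile salts, at 0.75 g per liter (0.075%). Per the labels' protocols, 200 ml of MRSc medium was seeded at 1%, held at 37 °C without oxygen, and collected in mid-exponential growth at an optical density at 600 nm of 0.6. RNA was extracted with TRIzol, depleted of ribosomal RNA with a RiboMinus kit, and made into a library for SOLiD sequencing, which reads DNA by ligation. The labels give 1 library per condition, and groups were taken from the stress treatment label.

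Each deposited table lists 1877 gene models, of which 1813 carry a numbered locus tag, 55 are tRNA models and 9 are rRNA models by their identifiers. Per the file headers, the deposited read counts are split into reads within exons (inside reads), reads at an exon-intron boundary (boundary reads) and reads on the reverse strand (antisense reads). No gene model has an intron, so boundary reads are taken here to be reads that cross the edge of a gene model, a reading that the headers do not state. Inside and boundary reads summed to the count on the gene in all 1877 models of both tables. Per the file headers, the authors computed RPKM from the inside reads, the gene length and the total of uniquely mapped reads. In both tables all 1877 RPKM values were recovered from 1 library total, within 0.1% or 0.02 RPKM. That total was 16275704 uniquely mapped reads for the control library and 19002672 for the ox-bile library. The aligner, its settings and the genome build are not given in the sources used here, and the tables hold no coordinates.

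The analysis used the inside counts. The numbered genes held 12858229 inside reads in the control library and 15048968 in the ox-bile library, and the 55 tRNA models held 0.271% and 0.306% of all inside reads. The tRNA and rRNA models were left out of the library totals. Each gene's ratio is the log2 of its ox-bile count over its control count, after division by the library total, with a pseudocount of 0.5 reads. Genes with fewer than 20 inside reads over both libraries were left out, which removed 53 numbered genes and left 1760. With 1 library per condition there is no estimate of the spread between cultures, so no test between conditions was made and no p-value is given. Genes were called by size alone, at a ratio of at least 2-fold in either direction. The 95% interval of each ratio is exact (Clopper-Pearson, conditional on the gene's summed reads), and intervals of shares are Wilson intervals. The intervals of ratios and shares cover counting error only, since amplified reads are not independent molecules and differences between cultures are not measured. The 95% interval given for a correlation comes from Fisher's z transformation. It takes gene pairs as independent, which they are not, and does not cover counting error. A count of 0 allows up to 3 reads, or 0.233 CPM (counts scaled to the library total) in the control library and 0.199 CPM in the ox-bile library.

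The calling step was tested on simulated data for this comparison, with counts drawn from the libraries' own means and counting noise only, over 1758 genes that passed the filter. Of 100 genes changed 3-fold, 99 were called in the right direction, as were 99 of 100 genes changed 6-fold, of which 1 was removed by the filter on low counts. Of 1559 unchanged genes that passed the filter, 1 was called. The 95% intervals held the simulated ratio for 95.1% of genes.

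Neighbouring genes were compared in locus-tag order, which both tables follow without exception. Adjacent, upstream, downstream and facing genes are named on the assumption that tag numbers follow gene position and rise along the plus strand. This could not be checked without coordinates. Spearman's rho between each measured gene and the next was set against 10000 shuffled orders. A run was defined as 3 or more consecutive measured genes on 1 strand that were all called in the same direction, and this definition was chosen after the data had been seen. The tRNA models were compared with 10000 random lists of numbered genes of the same size, matched on mean level in 10 bins. These comparisons describe the 2 libraries, since genes are not independent replicates.

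The files do not pair the locus tags with gene names, and 0 of the 1877 identifiers matched the reference gene table used here, which covers another strain of the species. Of the 37 gene lists fixed before the data were examined, only 1, the RNA list, could be filled, through the tRNA and rRNA identifiers. The naming rule fixed before the data were examined took the 12 highest and the 12 lowest ratios among numbered genes with a mean level at or above the 25th percentile, list members, bile salt hydrolases and the 5 most abundant genes per library. Because the identifiers could not be paired with gene names, only the first 2 genes in each direction are given by locus tag and the others are summarised. Neighbours of these genes and the single abundant genes described by length were chosen after their values had been seen.

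Alternatives fixed before the data were examined were TMM and median-of-ratios factors from edgeR, the RNA models kept in the total, pseudocounts of 0.05 and 5, no filter on low counts, the lower 50% of genes left out, a 4-fold threshold, and a counting interval wholly beyond 1. Counts with boundary reads (also for the tRNA calls), the authors' RPKM with a pseudocount of 1, and totals without the 5 most abundant genes were added afterwards. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. GC content was not examined, because no sequence was used here.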

Results

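To profile how *B. longum* BBMN68 transcripts differ when the cells grow with bile, RNA was sequenced from 1 control culture and 1 culture grown with 0.075% ox-bile. The control library held 12858229 reads inside numbered genes and the ox-bile library held 15048968. The median numbered gene had 1747 reads in the control library and 1980 in the ox-bile library. Reads were spread unevenly over genes in both: the 5 most abundant genes took 15.4% of the control reads and 16.8% of the ox-bile reads, and the 50 most abundant took 43.7% and 46.2%. Gene levels in the libraries were correlated across the 1760 measured genes (Spearman's rho = 0.892, across genes). There are no replicate libraries, so every difference below is between these 2 libraries and has no replicate check.

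The first comparison asked which genes differed in level between growth with and without ox-bile. Of the 1760 measured genes, 224 (12.7%) were at least 2-fold higher in the ox-bile library and 347 (19.7%) were at least 2-fold lower, while 1189 lay within 2-fold. At 4-fold, 34 genes were higher and 96 were lower. For 224 of the higher and 346 of the lower genes the 95% counting interval lay wholly beyond 1, and for 183 and 282 it lay wholly beyond 2-fold. The median gene had a log2 ratio of -0.11 when libraries were scaled by their totals. TMM factors moved all ratios up by 0.11 and gave 280 higher and 297 lower genes, and median-of-ratios factors moved them by 0.12 and gave 285 and 293, so the excess of lower genes at 2-fold depended on the scaling.

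**Figure D1:**
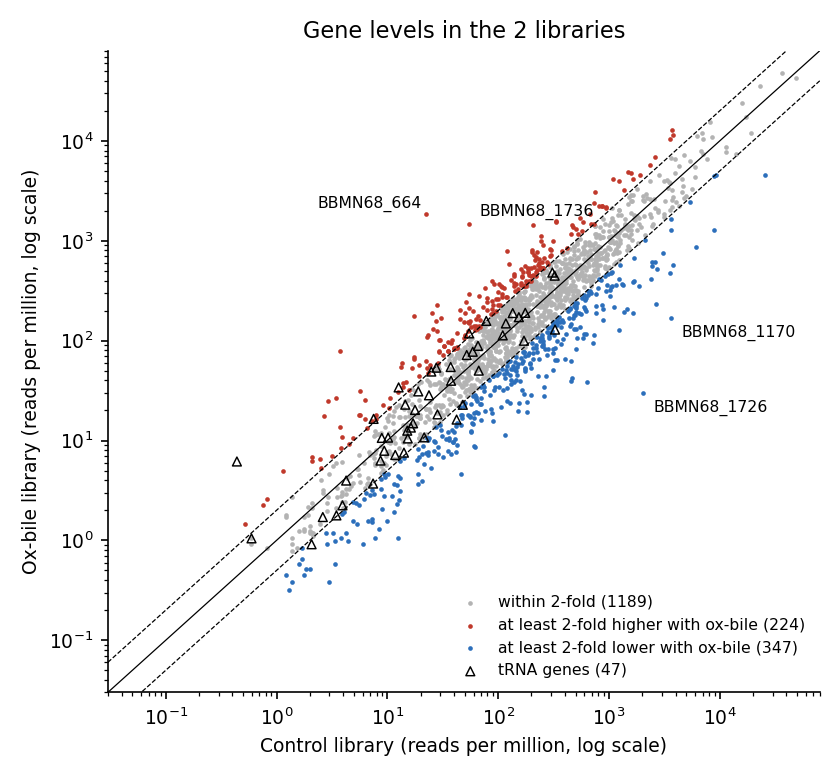
Level of each measured gene in the control library (x axis) and in the ox-bile library (y axis), in CPM on log scales, with 0.05 added to each value. Points are numbered genes, triangles are the 47 measured tRNA genes, the solid line marks equal levels and the dashed lines mark 2-fold differences. The 4 genes given by locus tag lie farthest from the line among well-measured genes.

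The 2 genes with the highest ratios had far more reads in the ox-bile library. The files do not pair locus tags with gene names, so their products are not given here. BBMN68_664, a 2052-base gene on the minus strand, had 285 reads in the control library and 28105 in the ox-bile library, a ratio of 84.1-fold (log2 ratio 6.39, 95% counting interval 6.23 to 6.57). The adjacent 111-base gene on the same strand, on its upstream side, was 21.1-fold higher, with 47 and 1173 reads, while the next gene downstream on that strand was 2.26-fold lower. BBMN68_1736, a 1350-base gene on the plus strand, had 706 and 22168 reads, a ratio of 26.8-fold (log2 ratio 4.74, interval 4.64 to 4.86). The next measured gene downstream of it on the same strand was 6.53-fold higher, with 34 and 263 reads. The 12 highest genes by the naming rule were between 4.93-fold and 84.1-fold higher, with a median of 6.75-fold, and each had at least 2025 reads over both libraries.

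The 2 genes with the lowest ratios each opened a block of neighbours that were lower together. BBMN68_1726, a 1158-base gene on the plus strand, had 26159 reads in the control library and 453 in the ox-bile library, and was 67.5-fold lower with ox-bile (log2 ratio -6.08, 95% counting interval -6.22 to -5.94). The 3 genes that follow it on the same strand were 16.3-fold, 11.4-fold and 4.86-fold lower, so that the ratio shrank gene by gene in the direction of transcription. BBMN68_1170, a 1326-base gene on the minus strand, had 46480 and 2510 reads and was 21.7-fold lower (log2 ratio -4.44, interval -4.50 to -4.38). The 3 genes that follow it in the direction of transcription had 1488 and 171, 1945 and 299, and 1968 and 360 reads, with log2 ratios of -3.34, -2.93 and -2.68. This block faces a run of 3 genes on the plus strand that were higher in the ox-bile library, with a summed ratio of 4.34-fold. The 12 lowest genes by the naming rule were between 7.68-fold and 67.5-fold lower, with a median of 10.6-fold. Of these, 7 lay in runs, some of them in the same run, against 2 of the 12 highest. Among all called genes, 112 of the 347 lower and 37 of the 224 higher genes lay in runs. Runs form more easily in the direction with more calls, and no shuffle was counted by direction.

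Among the 50 most abundant genes, 5 were at least 2-fold higher in the ox-bile library and 6 were lower, and with TMM factors 6 were higher and 4 were lower. The 3 lowest log2 ratios in this group were -2.81, -2.78 and -2.48. The last of these belonged to a 1317-base gene with 326800 reads in the control library, the third most abundant there, and 68446 in the ox-bile library. The highest ratio in this group was 3.49-fold, in a 2037-base gene with 47323 and 193148 reads. The 5 most abundant genes of each library had 3 members in common, and the log2 ratios of the 7 genes concerned ran from -2.48 to 0.61. Calls also depended on level. In the least abundant 25% of measured genes, 129 of 440 were lower and 47 were higher, with a median log2 ratio of -0.43, while in the most abundant 25%, 62 were lower and 58 were higher. With TMM factors the least abundant group still had 114 lower and 54 higher genes. Ratios showed no trend with coding length (rho = -0.00198 across genes), and genes of the plus and minus strands had median log2 ratios of -0.12 and -0.11.

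The second comparison asked whether neighbouring genes differed together. Across 1246 adjacent pairs on the same strand, Spearman's rho between the log2 ratios was 0.524, above the highest value in 10000 shuffled orders (0.110). Across 513 adjacent pairs on opposite strands it was 0.0854, just inside the central 95% of shuffled orders (-0.0876 to 0.0860), and 261 of the 10000 orders gave a value as large. Over all 1759 adjacent pairs it was 0.384. These are 3 correlations across genes, which are not independent replicates. In total, 149 of the called genes (26.1%) fell into 40 runs of 3 or more consecutive genes on 1 strand called in the same direction, where shuffled calls gave a median of 8 runs and at most 17. Shuffled runs held a median of 24 genes in total and at most 61. The longest observed run held 8 genes, and the single longest run in any of the 10000 shuffles held 10. How often a shuffle reached 8 was not counted. Of the 40 observed runs, 30 were lower in the ox-bile library and held 112 genes, and 10 were higher and held 37 genes. More genes were called lower (347) than higher (224), which by itself gives more lower runs. Shuffled runs were not counted by direction, so this split has no shuffled value beside it. With TMM factors there were 41 runs, 26 lower and 15 higher.

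**Figure D2:**
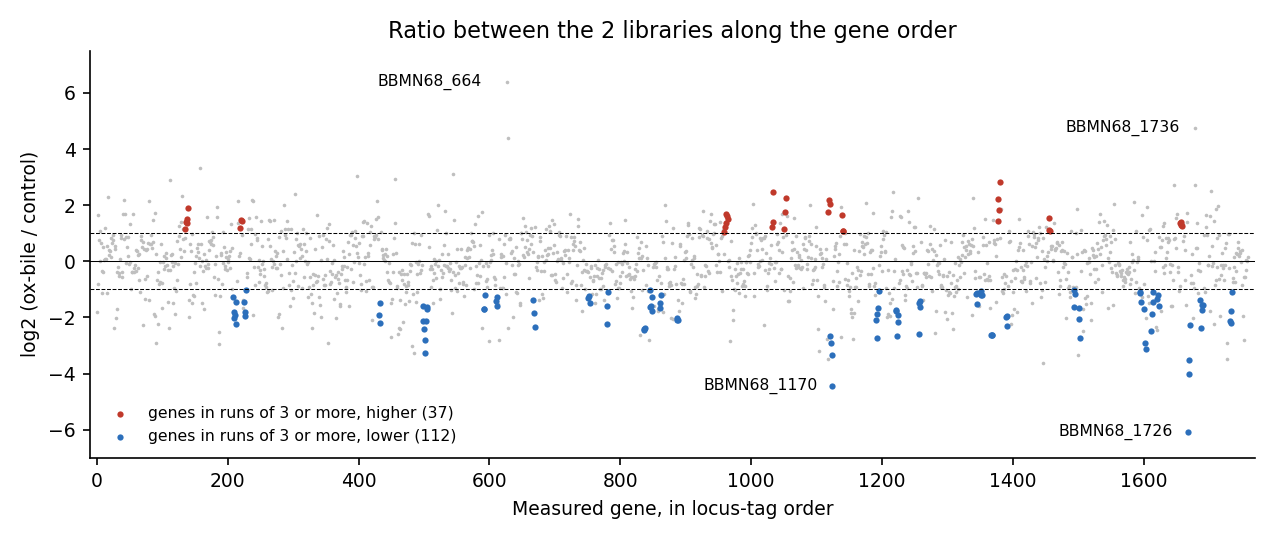
Log2 ratio of ox-bile over control (y axis) for the 1760 measured genes in locus-tag order (x axis). Grey points are single genes, coloured points are genes in the 10 higher and 30 lower runs, and the dashed lines mark 2-fold. By eye, a wide stretch of the order holds lower runs and no higher run when libraries are scaled by their totals. This stretch was not tested against shuffled orders and was not examined with TMM factors.

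The longest run held 8 genes on the minus strand that were lower in the ox-bile library, with log2 ratios from -3.27 to -1.60 and 105954 reads in the control library against 27392. The longest higher run held 6 genes on the minus strand, with log2 ratios from 1.05 to 1.69 and 13610 reads against 44001. A higher run of 4 minus-strand genes had the largest summed ratio among the higher runs, 4.67-fold, with 8912 and 48677 reads. The run with the most reads was a lower run of 4 plus-strand genes, with 353437 reads against 79044, a summed ratio of 5.23-fold. The 1317-base abundant gene described above supplied most of its reads.

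**Figure D3:**
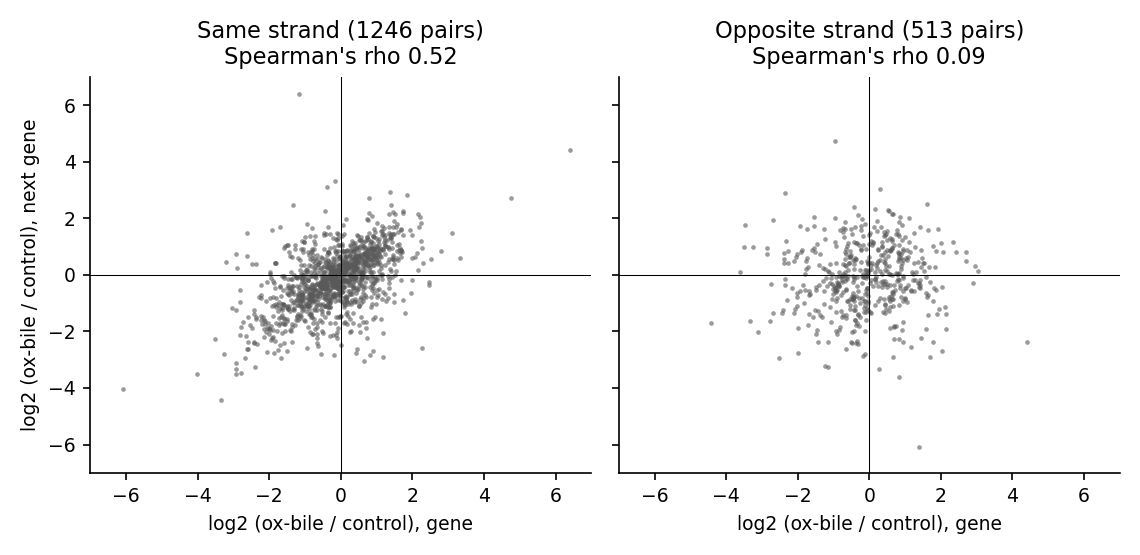
Log2 ratio of each measured gene (x axis) against that of the next gene in locus-tag order (y axis), for neighbours on the same strand (left, 1246 pairs) and on opposite strands (right, 513 pairs). Each point is 1 pair, and the points follow the diagonal on the left (rho = 0.524) and not on the right (rho = 0.0854).

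Stable RNAs formed the one gene class that the identifiers name. Of 55 tRNA genes, 47 had enough reads, and 5 of these were at least 2-fold higher in the ox-bile library, 6 were lower and 36 lay within 2-fold. With TMM factors 7 were higher and 3 were lower. With boundary reads included, 4 of the higher and 5 of the lower genes kept their calls, and no other tRNA gene was called. The higher gene that lost its call had 1005 and 2372 inside reads but 37336 and 24031 reads in all, and its log2 ratio went from 1.01 to -0.86. The lower gene that lost its call had 734 and 728 reads in all, with a log2 ratio of -0.23. The median log2 ratio of the 47 genes was 0.08 (quartiles -0.63 and 0.51). This median lay at percentile 98.6 of random lists of numbered genes matched on level, whose medians fell between -0.68 and 0.02 in 95% of draws. Against random lists made of stretches of neighbouring genes, which were not matched on level, it lay at percentile 83.2. The tRNA gene with the largest ratio had 5 reads in the control library and 92 in the ox-bile library. Reads of near-identical tRNA copies could be lost or split, because only uniquely mapped reads were used for RPKM. None of the 9 rRNA genes had an inside read in either library (0 reads). Likewise 15 numbered genes had 0 inside reads in both libraries, and 14 of them shared their exact length with another such gene, in sets of 5, 5, 2 and 2, so their levels are not known from unique reads.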

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

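The tests of wrong-strand reads and of ox-bile itself, and the shares without the genes richest in antisense reads, were chosen after the antisense totals had been seen. Reads on the strand opposite a gene were set aside as of no significance in the file headers and enter no comparison above. They drew attention because these unused reads differed between the libraries. Of 1479 numbered genes with at least 20 antisense reads over both libraries, 92 had at least 2-fold more antisense reads, relative to the library total, in the ox-bile library than in the control library, and 617 had at least 2-fold fewer. The median log2 ratio of antisense reads over these genes was -0.77. With TMM factors the counts were 111 and 544 and the median was -0.65. More than 50% of the reads lay on the antisense strand for 170 of these genes in the control library and for 154 in the ox-bile library, and 117 genes were in both sets.

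The antisense share of all reads on gene models was 3.12% in the control library (95% Wilson interval 3.11 to 3.13%) and 1.89% in the ox-bile library (1.89 to 1.90%), a ratio of 0.607. Wrong-strand reads made in library preparation would follow the sense reads of every gene, but the 100 most abundant genes had a median antisense share of 0.0793% in the control library, which argues against them as the cause. Genomic DNA would spread the control excess over genes by length, but 181 genes (10% of the numbered genes) held 80.5% of the summed excess, which argues against DNA as the whole cause. A smaller part from DNA stays open, since 74.2% of the numbered genes had more antisense reads, relative to the library total, in the control library. The gene richest in antisense reads, 1086 bases long, had 47106 in the control library and 10124 in the ox-bile library, and without the 5 richest genes the ratio was still 0.701, so a few loci do not account for all of it. An effect of ox-bile stays open and cannot be told apart from a difference between any 2 cultures or libraries, since there is 1 library per condition (ratio 0.607).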

How the results depend on the processing

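The 2-fold counts stayed within 1.5 times of 224 higher and 347 lower genes under 10 of 12 alternatives each. They moved to 124 higher and 146 lower when the lower 50% of genes was left out, and to 34 and 96 at 4-fold, as fewer genes can pass either. Scaling shifted the balance: lower genes were 60.8% of all calls with library totals and 51.5% with TMM factors. TMM factors bring the median gene to about 0, which by itself moves this balance, so whether the excess of lower genes comes from scaling by totals cannot be told apart from a real shift. With TMM factors lower genes were still more numerous at 4-fold (42 higher, 78 lower) and in the least abundant 25% of genes (54 and 114), but not in the other genes (226 and 183). The median tRNA log2 ratio ranged from 0.07 to 0.31 over 10 alternatives, the highest with only 6 tRNA genes left, but its percentile fell from 98.6 to 83.2 when random lists were built from stretches of neighbouring genes not matched on level; the cause was not tested. Matching on length was not run, because only 8 measured numbered genes are as short as the longest tRNA (90 bases). The neighbour correlation of 0.384 was 0.524 for same-strand pairs, 0.0854 for opposite-strand pairs, 0.372 without a filter and 0.317 without the lower 50% of genes. For the 4 genes given by locus tag, log2 ratios over 10 alternatives were 6.24 to 6.52 for BBMN68_664 and 4.71 to 4.87 for BBMN68_1736. They were -6.08 to -5.96 for BBMN68_1726 and -4.44 to -4.32 for BBMN68_1170. All 4 genes kept their direction, but these alternatives could not test it. Changes of filter leave a gene's own ratio as it was, and median-of-ratios factors moved all ratios by only 0.12. With TMM and median-of-ratios factors, BBMN68_1736 and BBMN68_1170 moved outside the counting intervals of their main ratios. With TMM factors the values were 4.859, above an upper limit of 4.856, and -4.323, above -4.38. No paired analysis was possible because each condition has 1 library, and no library could be left out for the same reason. Counting intervals lay wholly beyond 2-fold for 183 of the 224 higher and 282 of the 347 lower calls, so at this depth the other calls lie within counting error of the threshold, and the spread between cultures was not measured. Boundary reads, RPKM, totals without the 5 most abundant genes, opposite-strand pairs and the other neighbour filters were chosen after seeing the data.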

Other observations

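The tests of gene order, of regional bias and of the first gene in a run, and the boundary shares without 1 gene, were chosen after the values they concern had been seen. Boundary reads, taken here to cross the edge of a gene model, made up 2.70% of the reads on gene models in the control library (95% Wilson interval 2.70 to 2.71%) and 2.11% in the ox-bile library (2.11 to 2.12%). A single tRNA gene supplied 10.1% of all boundary reads in the control library and 6.64% in the ox-bile library, with 36331 and 21659 boundary reads against 1005 and 2372 inside reads. Without it the shares were 2.44% and 1.98%. In 4 tRNA genes with at least 20 boundary reads in the control library, more than 50% of the reads crossed the edge in both libraries.

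Same-strand neighbours had correlated ratios (rho = 0.524, above the 0.110 reached in 10000 shuffled orders), so an arbitrary gene order is argued against. A bias of whole regions would act on both strands, but opposite-strand neighbours had rho = 0.0854. Over 292 pairs with few boundary reads rho was 0.484 (95% interval 0.391 to 0.567), but this cannot test reads shared across gene edges. The ratios use inside reads only, so reads taken to cross an edge were already left out. Reads counted inside overlapping gene models were not tested, since gene coordinates are not given. Transcripts that span several genes are a candidate explanation: the median absolute difference in log2 ratio was 0.43 in 342 pairs rich in boundary reads and 0.52 in the others, a difference of -0.0930 where shuffled classes gave -0.0758 to 0.0735. The difference was small and the pairs were not matched on level. Shuffling took the pairs as independent, but consecutive pairs share a gene, so the shuffled range may be too narrow. Pairs with few boundary reads were still correlated, so this comparison gives the candidate limited weight. In the blocks led by BBMN68_1726 and BBMN68_1170 the first gene differed most, but over the 40 runs this held for 11, where random positions gave 6 to 17, so the data show no general rule of that kind.

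A hypothesis for the antisense reads is that many come from transcripts of a facing gene that run past its end. Genes followed, on their downstream side, by a gene on the opposite strand (522 genes) had a median antisense share of 14.6% in the control library, against 2.38% for the other 957 genes, a difference of 12.2 percentage points where shuffled classes stayed between -1.14 and 1.24. Over 502 such genes, the ratio of their antisense reads between the libraries followed the ratio of the facing gene's own reads (rho = 0.669). Shuffled neighbours gave at most 0.172. The antisense ratio showed little relation to the ratio of the gene's own sense reads (rho = 0.012). That value covers those of the 502 genes whose own sense reads passed the filter. Both results are what such transcripts would give. They concern where antisense reads lie, and whether such transcripts account for the lower antisense share in the ox-bile library was not tested. The median log2 ratio was -0.77 for antisense reads over 1479 genes and -0.11 for sense reads over 1760 genes. Gene models that overlap at their ends may also give a correlation of this kind. This was not tested, since the tables hold no coordinates.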
